A study of Mus musculus with 105 samples.

How the data were processed

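The series measured gene expression in tail skin of untreated backcross mice aged 8 weeks, labelled as lacking both copies of Hras. Per the labels, RNA was extracted with TRIzol and RNeasy columns, and biotinylated cRNA made from it was hybridised to an Affymetrix mouse gene array, with 1 array per mouse. The deposited values are on the log2 scale, and per the labels the authors made them with RMA, which corrects background, normalises quantiles between arrays and summarises the probes of a probe set. The version of RMA, whether all arrays were normalised together, and any adjustment for plate are not given in the sources used here. The table had 35556 probe sets on 105 arrays, 46 of females and 59 of males, with 47, 47 and 11 arrays on plates 1, 2 and 3. All 105 columns were matched to a sample.

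A total of 171 probe sets without a value on any array were left out. Of the 35385 others, 21201 carried exactly 1 gene symbol, 1881 several and 12303 none. Symbols were brought up to date with a gene table that held 99.8% of the Entrez identifiers, and the same table gave the order of genes along chromosomes. No genome build is named for the array files, so no positions are given. For each of the 1385 genes with more than 1 probe set, the brightest was used. Probe sets were kept when they lay above the array's 40th percentile on at least 46 arrays, the number of females, which left 21436 probe sets and 12579 named genes. Values that share a symbol with several genes were tested but not named. Genes that the array annotation does not name, and genes not analysed here, are missing from the lists.

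The 2 arrays marked as outliers in the labels were left out, both males on plate 2, so that 46 arrays of females and 57 of males were analysed. Array medians ranged from 4.71 to 4.87 and single values from 0.62 to 13.3. Labelled sex was checked against Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty, with 0 mismatches. The median correlation of each analysed array with the others was at least 0.948, and 2 arrays, male 7 on plate 1 and male 47 on plate 2, stood apart with a median below 0.97. The number of arrays limits the precision, and the median residual SD of a probe set was 0.243 log2.

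The groups, the gene lists, the tests, most of the alternatives and the rule for naming genes were fixed before the data were examined. The sexes were compared with limma 3.58.1 in R 4.3.3, with plate as a covariate, as female minus male, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The moderated F test of limma was used for plates, with sex as a covariate, and for the interaction of sex and plate. Simulated changes were added to 50 genes at each of 4 sizes to test the fit. It recovered 22% of changes of 0.1 log2, 68% of 0.2, 84% of 0.4 and 100% of 0.8, with 8 false calls among 21436 probe sets. Genes named in the sex comparison are the 12 largest called differences in each direction, every measured member of the Y-linked, X escape and Ras lists, and up to 4 members with the smallest p of each other list. For plates they are the 5 genes with the smallest p, for spread between mice the 20 with the largest residual SD, and for correlations up to 4 members of a list with the highest correlation to the rest of it.

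Fixed lists of marker and pathway genes were tested with limma's camera at its preset correlation of 0.01, where they held at least 3 measured genes, and camera with an estimated correlation and fry were the alternatives. The p of single genes was also adjusted over the list alone. Where mean differences of a list are given, they are the differences of the mean over its genes per mouse, with plate in the model.

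Variation between mice was analysed on residuals after sex and plate were removed, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The mean pairwise correlation of each list was set against 10000 random lists of the same size matched on mean expression (one-sided). List scores, the mean of the members' standardised residuals, were correlated in 351 pairs with Pearson's r and Spearman's rho, each with a two-sided permutation test of 100000 resamples and Benjamini-Hochberg adjustment over the pairs. The difference of each correlation between the sexes was tested with 10000 permutations of sex. Residuals of each named gene were fitted with 1 and with 2 normal groups, and a gene was placed in 2 groups when the BIC difference was above 10, the smaller group held at least 30% of the mice and the groups lay apart by at least 2 SD. On simulated data of 400 genes each, this placed 0% of genes without groups (normal or heavy-tailed), 27.8% with groups 3 SD apart and 97.2% with groups 4 SD apart. Skewed data without groups were not simulated, so the error rate for such genes is not known. Intervals of the SD are at the 95% level. Figures were drawn with matplotlib 3.10.9.

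Each comparison was repeated with the marked arrays included, without the plate term or the removal of sex and plate, without and with a stricter filter on dim probe sets (60th percentile), after quantile normalisation between arrays, with limma-trend and robust variances, with array weights, with the first principal component of the residuals as a covariate or removed, and within plates and within sexes, as far as each applied. For the sex comparison the mean of a gene's probe sets was also used. Leaving out the arrays that stood apart, and using only probe sets with 1 gene symbol, were added after the data had been seen. Chance was tested with 100 splits of the arrays, the real one included.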

Results

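Gene expression was measured in tail skin of untreated mice aged 8 weeks that are labelled as lacking both copies of Hras, a small GTPase of the Ras family. The mice came from a backcross: hybrid females of Mus spretus and the inbred strain FVB/N were mated to FVB/N males, so that each mouse carries its own mixture of the parental genomes. RNA of each mouse was hybridised to a separate Affymetrix mouse gene array, and the deposited table holds log2 values for 35556 probe sets on 105 arrays. The labels name the sex of each mouse and the plate it was run on. They mark 2 arrays of males on plate 2 as array outliers, which left 46 females and 57 males. Plate 1 held 21 females and 26 males, plate 2 held 19 and 26, and plate 3 held 6 and 5. Array medians lay between 4.71 and 4.87 on the log2 scale, and the correlation between any pair of arrays was between 0.930 and 0.988. The number of arrays limits the precision of the values below. No mice with a working copy of Hras were compared, and Hras itself was not analysed here, so the labelled genotype was not checked against the arrays.

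The comparison of the sexes asked which genes of the skin differ between female and male mice of this population. Xist, the RNA that coats the inactive X chromosome, was 7.15 ± 0.05 log2 (SE) higher in females (10.3 ± 0.37, SD, n = 46, against 3.20 ± 0.38, n = 57). The Y-linked genes Eif2s3y, Uty and Kdm5d were lower in females by -5.82 ± 0.05, -4.61 ± 0.04 and -3.59 ± 0.05. For each of these 4 genes the values of females and males did not overlap, and 0 arrays disagreed with their labelled sex. Sry, the testis-determining gene, differed by 0.06 ± 0.05 and did not pass the test (limma adjusted p = 0.533). All 6 measured genes known to escape X inactivation were higher in females (limma adjusted p between 3e-111 and 0.00066), and 6 of 6 passed adjusted over the list alone. After Xist these were Kdm6a (0.65 ± 0.03), Eif2s3x (0.57 ± 0.03), Kdm5c (0.40 ± 0.02), Ddx3x (0.25 ± 0.03) and Pbdc1 (0.21 ± 0.04).

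In all, 666 of 21436 probe sets differed between the sexes, 359 higher in females and 307 higher in males (limma with plate in the model, Benjamini-Hochberg adjusted p under 0.05). Of 12579 named genes, 301 were higher in females and 235 in males. The differences were mostly small, with a median size of 0.20 log2 among the named genes, and 19 genes reached 1.5-fold in females and 7 in males. X-linked genes were called more often than others (10.1% of 366 against 4.06%, two-sided Fisher's exact test p = 9.3e-07, across genes, which are not independent replicates), with 32 higher in females and 5 higher in males. Of the 536 called genes, 435 had the same direction on plate 3. All had it on plates 1 and 2, which the choice of genes by the pooled fit nearly fixes, since these plates hold most of the arrays. Fitted within a plate, plate 1 gave 81 probe sets, plate 2 gave 43 and plate 3 gave 6.

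The largest autosomal difference was that of Cyp2g1, a cytochrome P450, which was 6.65-fold higher in females (2.73 ± 0.26 log2, SE, limma adjusted p = 3.1e-14). Its difference was 2.74 on plate 1, 2.82 on plate 2 and 2.34 on plate 3, and 45 of 46 females lay above the median male. Akr1c18, which encodes a 20-alpha-hydroxysteroid dehydrogenase, was 0.81 ± 0.11 higher in females (limma adjusted p = 6.2e-08), with 42 of 46 females above the median male. Hsd11b1, whose enzyme regenerates active glucocorticoid, was lower in females by -0.75 ± 0.10 (limma adjusted p = 3.6e-08), with 44 of 46 females below the median male. Carns1, which encodes carnosine synthase, was 0.90 ± 0.13 higher in females (limma adjusted p = 6.3e-07), with 41 of 46 females above the median male.

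Among the other genes with the largest female excess were the secreted phospholipase Pla2g2a (1.01 ± 0.25), the bone sialoprotein gene Ibsp (0.98 ± 0.28), the cartilage matrix gene Chad (0.91 ± 0.26) and Angptl7 (0.81 ± 0.22). Serpinb6d (0.78 ± 0.14), the hedgehog-binding gene Hhip (0.74 ± 0.17), the predicted gene Gm11564 (0.73 ± 0.22) and a probe set annotated to the microRNA gene Mir675 (0.66 ± 0.11) followed. The limma adjusted p of these 8 genes lay between 5.9e-05 and 0.0418, and between 35 and 40 of 46 females lay above the median male. On plate 3, Chad (-1.03) and Hhip (-0.11) pointed the other way, and Gm11564 no longer passed without the filter on dim probe sets.

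After the Y-linked genes and Hsd11b1, 8 genes made up the rest of the 12 with the largest male excess. The protease inhibitor gene Stfa3 was lower in females by -0.97 ± 0.20, and the secretoglobin genes Scgb2b27 and Scgb1b27 by -0.88 ± 0.15 and -0.63 ± 0.12. Lcn2, which encodes an iron-siderophore binding protein of innate defence, differed by -0.56 ± 0.16, and the interleukin gene Il1f6 by -0.47 ± 0.13. Rarres1 (-0.45 ± 0.07), Tlcd3b (-0.44 ± 0.08) and the cornified envelope gene Sprr2d (-0.44 ± 0.10) followed, with limma adjusted p between 8.15e-06 and 0.0371 for these 8 genes and between 34 and 43 of 46 females below the median male. Sprr2d pointed the other way on plate 3 (0.16).

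**Figure D1:**
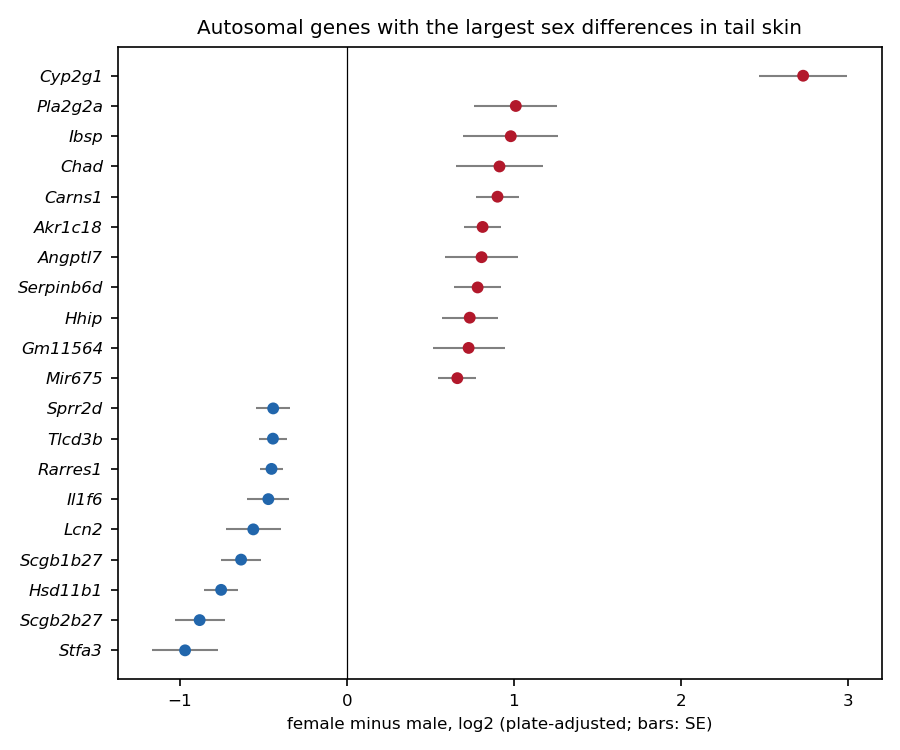
The 20 autosomal genes among the 12 largest differences in each direction. The horizontal axis gives female minus male on the log2 scale, adjusted for plate, points are estimates from 46 females and 57 males, bars are SE. Cyp2g1 stands at 2.73, and the male-biased genes lie between -0.97 and -0.44.

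Genes of the hair follicle were on average higher in females. The 9 measured hair shaft genes averaged 0.37 ± 0.13 log2 higher (camera adjusted p = 4.9e-06), and the 8 genes of the inner root sheath, the layer around the growing hair, 0.43 ± 0.14 higher (camera adjusted p = 3.2e-06). With an estimated correlation, the adjusted p was 0.19 for both lists. Males varied more than females in both list means. The SD was 0.81 against 0.47 for the hair shaft and 0.83 against 0.49 for the inner root sheath. Whether all males or only a part of them lay lower was not tested. Over all genes tested, the regulator of hair keratins Hoxc13 (0.19 ± 0.05) passed in the first list and the keratins Krt73 (0.51 ± 0.14) and Krt25 (0.43 ± 0.12) in the second. Adjusted over the list alone, 8 of 9 and 8 of 8 genes passed. Members of these lists varied together between mice (mean correlation 0.81 and 0.91), so they are not separate observations. The 12 follicle stem cell genes averaged 0.11 ± 0.03 higher (camera adjusted p = 0.0011, adjusted p = 0.19 with an estimated correlation). Of these, Cd34 (0.34 ± 0.08) and Lgr5 (0.27 ± 0.07) passed over all genes and 5 genes adjusted over the list alone. Across mice, Cd34 did not follow the rest of its list (r = 0.02, against 0.47 for Lgr5). These 3 list means were higher in females on each plate, by 0.58, 0.21 and 0.13 on plates 1, 2 and 3 for the hair shaft, 0.70, 0.17 and 0.30 for the inner root sheath and 0.13, 0.10 and 0.10 for the stem cells.

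Among lists of tissues beneath the epidermis, camera with its preset correlation called tendon, adipocytes, smooth muscle, mast cells, skeletal muscle, fibroblasts and endothelium higher in females. None of these calls held with an estimated correlation, and the mean differences of skeletal muscle, fibroblasts and endothelium were within 2 SE. The 7 tendon genes had the largest mean difference (0.47 ± 0.13, camera adjusted p = 3.2e-06, adjusted p = 0.13 with an estimated correlation), and all 7 passed adjusted over the list alone. Over all genes tested, Chad, the tendon membrane gene Tnmd (0.48 ± 0.11) and the tendon transcription factor Mkx (0.36 ± 0.08) passed. The 11 adipocyte genes averaged 0.25 ± 0.07 higher (camera adjusted p = 2.1e-05, adjusted p = 0.19 with an estimated correlation). The muscle and fat carbonic anhydrase gene Car3 (0.66 ± 0.20), the resistin gene Retn (0.41 ± 0.12) and the adiponectin gene Adipoq (0.37 ± 0.09) passed over all genes, and 7 adjusted over the list alone. Without the filter on dim probe sets, Car3 and Retn no longer passed.

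The 8 smooth muscle genes averaged 0.21 ± 0.07 higher (camera adjusted p = 0.00021, adjusted p = 0.19 with an estimated correlation), with 1 passing over all genes (Tagln, 0.27 ± 0.08) and 4 adjusted over the list alone. The 8 mast cell genes averaged 0.19 ± 0.07 higher (camera adjusted p = 0.00101, adjusted p = 0.25 with an estimated correlation), with the receptor gene Kit (0.19 ± 0.05) passing over all genes and 4 adjusted over the list alone. Of 13 skeletal muscle genes 0 passed over all genes and 0 adjusted over the list alone, and all 13 differences were positive (mean 0.44 ± 0.23, camera adjusted p = 0.00021, adjusted p = 0.42 with an estimated correlation). These genes varied almost as 1 between mice (mean correlation 0.92), so their shared sign adds little. The 13 fibroblast and matrix genes averaged 0.11 ± 0.07 higher (camera adjusted p = 0.0081, adjusted p = 0.52 with an estimated correlation). Lum (0.42 ± 0.12), Mfap5 (0.30 ± 0.09) and Postn (0.18 ± 0.05), which encode extracellular matrix proteins, passed over all genes, and 4 adjusted over the list alone. The 11 endothelial genes averaged 0.11 ± 0.06 higher with 0 passing on either adjustment (camera adjusted p = 0.0135, adjusted p = 0.52 with an estimated correlation).

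Lists of the interfollicular epidermis were lower in females. The 14 genes of stressed keratinocytes, which are induced in wounded or inflamed epidermis, averaged -0.40 ± 0.13 (camera adjusted p = 1.5e-05, adjusted p = 0.19 with an estimated correlation). Stfa3, Il1f6, Sprr2d and the interleukin gene Il1f9 (-0.27 ± 0.06) passed over all genes, and 8 adjusted over the list alone. The 14 cornification genes averaged -0.10 ± 0.03 (camera adjusted p = 2.9e-05, adjusted p = 0.19 with an estimated correlation). Krt1 (-0.15 ± 0.04) and the transglutaminase gene Tgm3 (-0.19 ± 0.05) passed over all genes, and 7 adjusted over the list alone. The 10 basal epidermal genes averaged -0.06 ± 0.02 (camera adjusted p = 0.0085, adjusted p = 0.31 with an estimated correlation), with the laminin gene Lamb3 (-0.20 ± 0.04) and the keratin gene Krt14 (-0.08 ± 0.02) passing on both adjustments.

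The 13 oxidative phosphorylation genes averaged -0.04 ± 0.01 in females (camera adjusted p = 0.0143, adjusted p = 0.25 with an estimated correlation), with 0 passing over all genes and 2 adjusted over the list alone. The 13 immediate early genes averaged -0.10 ± 0.06 (camera adjusted p = 0.0117, adjusted p = 0.42 with an estimated correlation), with 0 passing on either adjustment.

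Of 30 lists with at least 3 measured genes, 17 were called by camera with its preset correlation, the X escape and Y-linked lists (camera adjusted p = 1.1e-72 and 3.4e-83) among them, and these 2 were the calls that held with an estimated correlation. Other splits of the mice called up to 12 lists. On plate 3, with 11 arrays, 9 of the 15 called list means outside the sex-linked lists took the opposite sign: basal epidermis (0.005), stressed keratinocytes (0.10), adipocytes (-0.02), fibroblasts and matrix (-0.05), skeletal muscle (-0.56), smooth muscle (-0.02), tendon (-0.18), endothelium (-0.02) and oxidative phosphorylation (0.03). All 15 had the pooled sign on plates 1 and 2, where skeletal muscle, for example, differed by 0.46 and 0.68 and stressed keratinocytes by -0.27 and -0.66.

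The other 13 lists did not pass. Their mean differences were 0.18 ± 0.06 for tail scale keratins (median 0.02, with Krt31 at 0.50 ± 0.18, Krt84 at 0.02 ± 0.02 and Krt36 at 0.01 ± 0.03), 0.02 ± 0.07 for the sebaceous gland, 0.06 ± 0.07 for melanocytes, 0.02 ± 0.07 for antigen presentation and 0.02 ± 0.09 for macrophages. They were -0.07 ± 0.06 for the interferon response, -0.04 ± 0.04 for proliferation, -0.02 ± 0.02 for heat shock and -0.05 ± 0.03 for cholesterol synthesis, in which the sterol enzyme genes Cyp51 (-0.24 ± 0.05) and Lss (-0.20 ± 0.06) passed over all genes and 3 adjusted over the list alone. Adjusted over the list alone, 1 member passed in each of the tail scale, sebaceous gland, proliferation, heat shock and ERK feedback lists. The clock lists differed by 0.02 ± 0.05 for the Per and Dbp arm and -0.005 ± 0.03 for the Bmal1 arm. The ERK feedback list, genes switched on by signalling downstream of Ras, had a mean of 0.004 ± 0.03 but a median of -0.01 and a camera direction below 0, and Ier3 (-0.22 ± 0.04) was its 1 member passing over all genes. For macrophages the median was -0.001 where mean and camera direction were positive. The Ras list averaged 0.06 ± 0.03, with Mras at 0.15 ± 0.05 (limma adjusted p = 0.053), Rras at 0.14 ± 0.06, Rras2 at -0.06 ± 0.04 and Nras at -0.001 ± 0.03, and 2 of 4 passed adjusted over the list alone. Mras passed over all genes in 8 alternative settings. Schwann cells, T cells, B cells and red blood cells had 2 measured genes each and were not tested as lists. Among these, the myelin gene Pmp22 was 0.31 ± 0.08 higher in females (limma adjusted p = 0.0097).

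**Figure D2:**
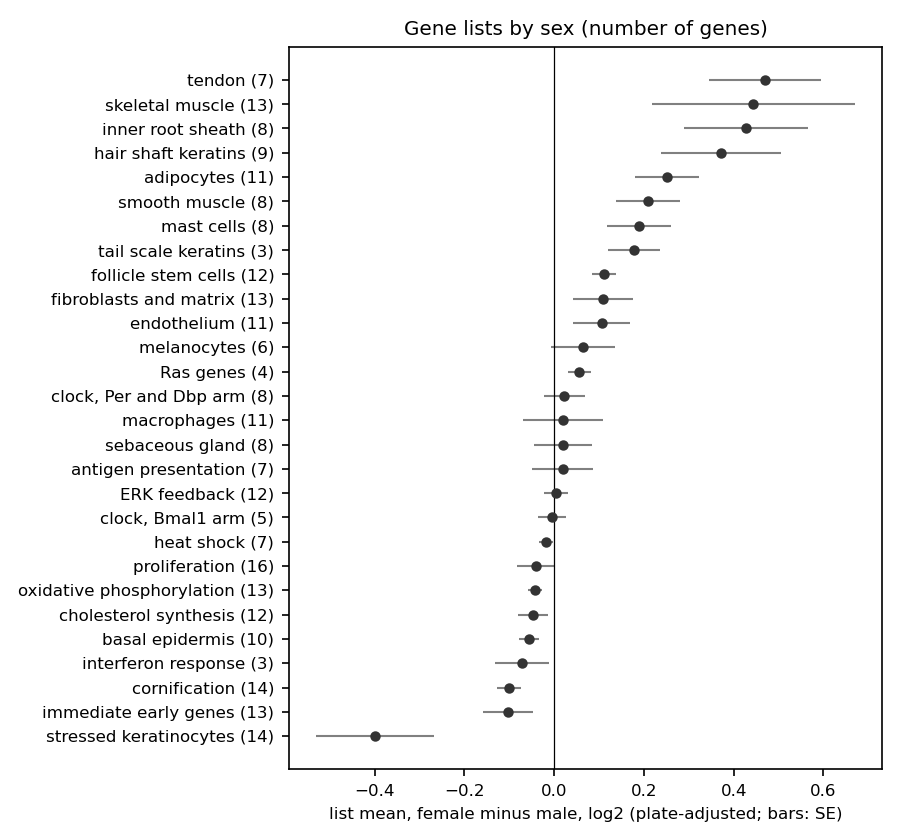
Mean sex difference of each gene list with at least 3 measured genes, sex-linked lists left out. The horizontal axis gives female minus male of the list mean on the log2 scale, adjusted for plate, points are estimates from 46 females and 57 males, bars are SE, and the number of genes stands in brackets. Tendon lies highest at 0.47 and stressed keratinocytes lowest at -0.40.

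Whether the sex difference varied between plates was tested with the interaction of sex and plate. With limma, 0 probe sets passed, and 777 had an unadjusted p under 0.05 where 1072 of 21436 would by chance. limma-trend with robust variances also gave 0, and 1 probe set passed without the filter on dim probe sets and 1 without the 2 arrays that stood apart.

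Plate itself was compared as a technical batch. Only 4 probe sets differed between the plates (limma F test, adjusted p under 0.05), and the 3 named genes among them were Xist, Eif2s3y and Uty, all sex-linked (limma adjusted p = 1.2e-10, 1.2e-09 and 1.2e-08). Adjusted for sex, Xist on plate 3 lay -0.73 ± 0.08 log2 (SE) from the mean of all arrays, and Eif2s3y and Uty lay 0.61 ± 0.07 and 0.52 ± 0.06 above it. The other probe set was not one of those used for a named gene. Kdm5d had the next smallest p (limma adjusted p = 0.063) with an offset of 0.33 ± 0.07, and Mir181b-1 came next with a limma adjusted p of 1.00. Females on plate 3 averaged 9.48 for Xist against 10.5 on plate 1 and 10.4 on plate 2, and males averaged 2.62 against 3.30 and 3.22. For Eif2s3y both sexes were higher on plate 3, females at 3.19 against 2.48 and 2.53 and males at 9.02 against 8.33 and 8.33.

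**Figure D3:**
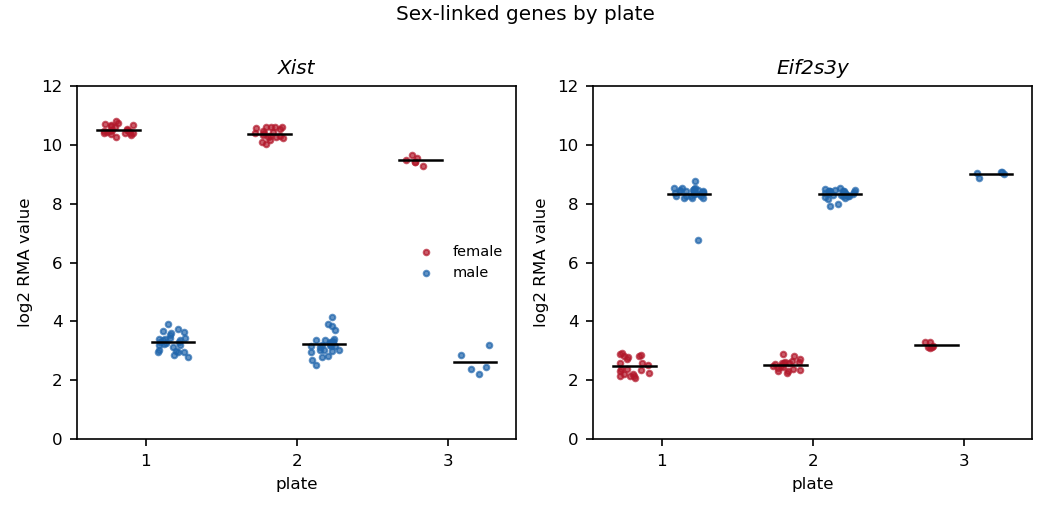
Log2 values of Xist (left) and Eif2s3y (right) on each plate, 1 point per mouse, females red and males blue, with horizontal bars at the group means. On plate 3 both sexes lie lower for Xist and higher for Eif2s3y than on plates 1 and 2.

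Because the mice share genotype label, age, tissue and treatment, the remaining comparison was how genes vary together between mice, after the differences of sex and plate were removed. Genes of a cell type or pathway rose and fell together in most lists. The mean correlation between members was 0.92 for 13 skeletal muscle genes, 0.91 for the inner root sheath, 0.81 for the hair shaft and 0.75 for fibroblasts and matrix. It was 0.70 for melanocytes, 0.70 for macrophages, 0.69 for endothelium, 0.56 for proliferation, 0.55 for tendon and 0.54 for mast cells. With the first principal component of all genes removed, the mean correlation fell to 0.23 for macrophages, 0.28 for endothelium and 0.48 for fibroblasts and matrix. Tendon and mast cells fell less, to 0.42 and 0.42. It stayed at 0.91 for skeletal muscle, 0.92 for the inner root sheath, 0.79 for the hair shaft, 0.69 for melanocytes and 0.54 for proliferation. The lead members were the muscle genes Ttn and Neb (r with the other members 0.99 and 0.99), the sheath keratins Krt71 and Krt25 (0.97 and 0.96), the collagens Col6a1 and Col6a2 (0.95 and 0.93), the endothelial genes Pecam1 and Eng (0.93 and 0.91) and the complement genes C1qc and C1qb of macrophages (0.92 and 0.91).

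Mean correlations were lower in the stressed keratinocyte (0.45), antigen presentation (0.45), smooth muscle (0.44), adipocyte (0.43) and cholesterol synthesis (0.43) lists, and in the Per and Dbp arm of the clock (0.45). They were 0.36 for immediate early genes, led by Egr1 and Fos (r with the other members 0.84 and 0.79), 0.34 for the interferon response, 0.33 for basal epidermis, 0.29 for cornification and 0.27 for the sebaceous gland. Follicle stem cells (0.15), oxidative phosphorylation (0.15), ERK feedback (0.19) and the Bmal1 arm of the clock (0.15) were weakest among the lists that passed. Against 10000 random lists matched on size and mean expression, 25 of 28 lists passed at an adjusted p under 0.05. For 20 of them the p was 0.0001, the smallest possible (adjusted p = 0.00014). Tail scale keratins (0.12, adjusted p = 0.33), heat shock (0.002, adjusted p = 0.64) and Ras genes (0.13, adjusted p = 0.084) did not pass. The random lists were not matched on spread between mice, which was larger in most marker lists. The median residual SD of skeletal muscle genes was 1.28 log2, above 100% of its random lists. For such lists a pass partly reflects this spread. Oxidative phosphorylation and ERK feedback passed with a median SD above only 12% and 58% of theirs. The interferon response and the Bmal1 arm did not pass on plate 1 alone (adjusted p = 0.34 and 0.17), in females alone (0.20 and 0.12) or without 2 more arrays that stood apart (0.092 and 0.073), and their mean correlations on plate 3 were -0.07 and -0.01. The Bmal1 arm also did not pass with the first principal component removed (adjusted p = 0.12) or with the marked arrays included (0.052).

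Lists were then correlated with each other over all mice, 351 pairs of 27 lists, with a two-sided permutation test of each. Hair shaft and inner root sheath were the closest pair (Pearson's r = 0.96, Spearman's rho = 0.96, and r = 0.96 without the 2 mice farthest from the median). Within plates 1, 2 and 3 it was 0.97, 0.96 and 0.99. The lists of dermal cells formed a block. Fibroblasts and matrix went with macrophages (r = 0.84, rho = 0.78, 0.80 without the 2 farthest, and 0.85, 0.85 and 0.62 within plates), with endothelium (r = 0.83, rho = 0.78, 0.80, and 0.86, 0.83 and 0.83) and with tendon (r = 0.76, rho = 0.80, 0.74, and 0.81, 0.70 and 0.78). Endothelium went with macrophages (r = 0.85, rho = 0.79, 0.80, and 0.85, 0.86 and 0.64). With the first principal component of all genes removed, this last correlation was 0.05.

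Sebaceous gland genes went with cholesterol synthesis genes (r = 0.65, rho = 0.58, 0.56 without the 2 farthest, and 0.57, 0.68 and 0.84 within plates 1, 2 and 3). Follicle stem cell genes went with ERK feedback genes (r = 0.59, rho = 0.63, 0.61, and 0.64, 0.56 and 0.43), and so did the inner root sheath (r = 0.53, rho = 0.58, 0.51, and 0.45, 0.66 and 0.59). Lead members here were Mc5r and the lipid enzyme gene Far2 (r with the other sebaceous genes 0.76 and 0.75). In the other lists they were the cholesterol enzyme gene Sqle (0.81 with its list), the stem cell factor gene Sox9 (0.62) and the ERK phosphatase gene Dusp6 (0.62). Skeletal muscle went with tendon (r = 0.57, rho = 0.62, 0.57, and 0.46, 0.69 and 0.65). Each r and rho of the pairs above had a permutation p of 1e-05, the smallest possible (adjusted p = 0.00011 for r and 0.00016 for rho).

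Cornification genes fell where endothelial genes rose (r = -0.49, rho = -0.40, -0.43 without the 2 farthest, and -0.51, -0.48 and -0.52 within plates) and where ERK feedback genes rose (r = -0.46, rho = -0.37, -0.42, and -0.55, -0.32 and -0.57). The permutation p was 1e-05 for both r (adjusted p = 0.00011), and 3e-05 and 0.00018 for rho (adjusted p = 0.00038 and 0.0018). With the first principal component removed, the correlation of cornification with endothelium was -0.23 and no longer passed (adjusted p = 0.072). In all, 117 pairs passed, 68 positive and 49 negative, and 81 of these had the same sign on all 3 plates. On plate 3 alone 1 pair passed, and by Spearman's rho 77 did. With the first principal component removed, 52 of the 117 still passed. In females alone 39 pairs passed and in males alone 111. The correlation differed between females and males in 0 pairs after adjustment. At an unadjusted permutation p under 0.05, which some of the 351 pairs reach by chance, it differed in 28.

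**Figure D4:**
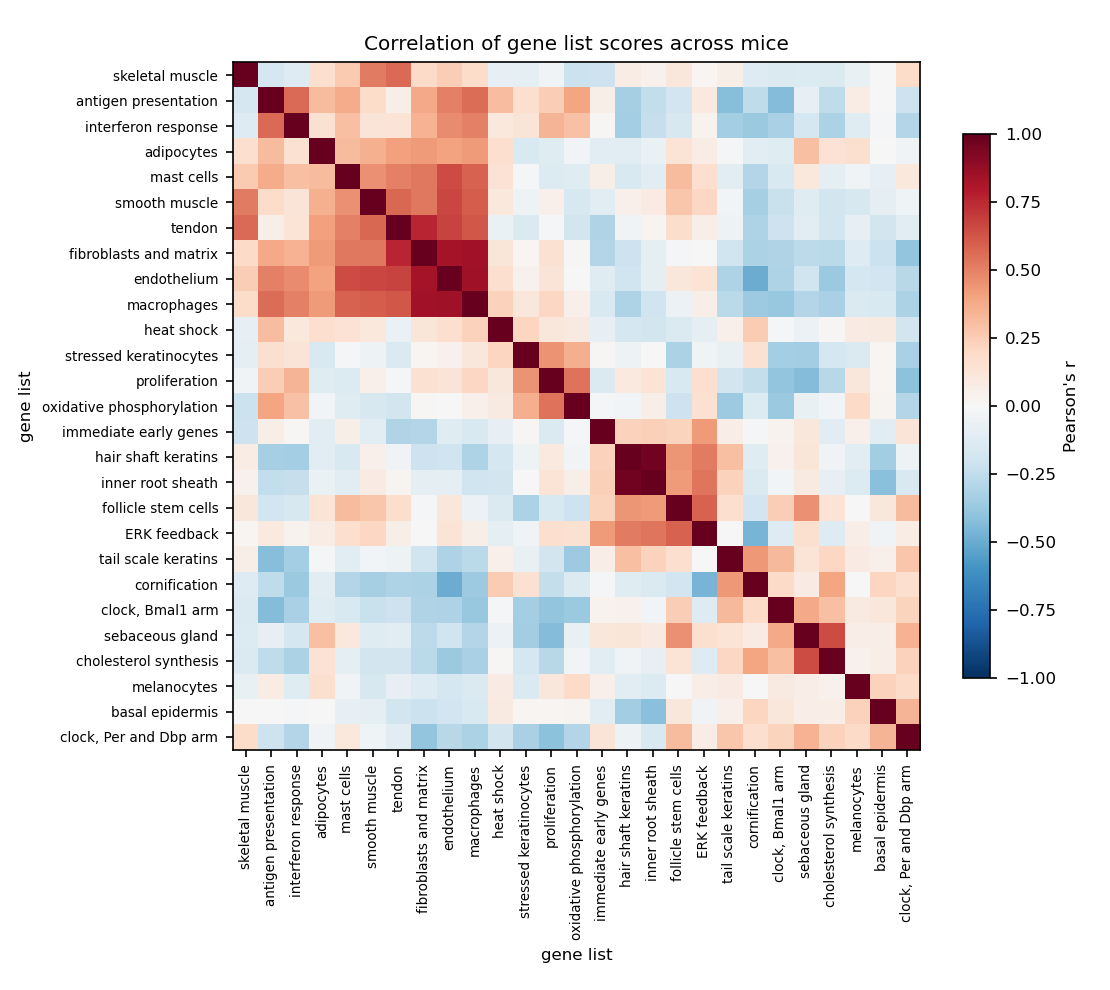
Pearson's r between the scores of 27 gene lists over 46 females and 57 males, after removal of sex and plate, on a colour scale from -1 (blue) to 1 (red), lists in clustered order on both axes. The block of fibroblasts, endothelium, macrophages, tendon and muscle lists stands apart from the pair of hair lists (r = 0.96).

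The relation of Nras to the ERK feedback list was computed to follow Ras signalling genes in these mice. Nras averaged 8.57 with a residual SD of 0.13 log2. Its correlation with the list was r = -0.06 (permutation p = 0.572) and rho = 0.07 (permutation p = 0.471), and r was 0.07 without the 2 farthest mice. Within plates 1, 2 and 3 it was -0.25, 0.22 and -0.12, and adjustment was not needed, since 1 of the 6 relations set out in advance was run. The other 5 involve genes not analysed here.

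After removal of sex and plate, the wound keratin Krt6b had the largest spread between mice, a residual SD of 2.08 log2 (95% interval 1.83 to 2.42), with values from 2.93 to 11.2, against a median residual SD of 0.22 over all genes. The antimicrobial gene Defb3 (2.00) and the calgranulin genes S100a8 (1.95) and S100a9 (1.5), all made in stressed epidermis, were also among the 20. Skeletal muscle gave Myl1 (1.73), Myh1 (1.66), Neb (1.41) and Atp2a1 (1.36). The sebaceous desaturase gene Scd3 had 1.77. Ces1f (1.82), the complement receptor gene Cr2 (1.79), Serpina3b (1.72), Igfl3 (1.65), Serpinb6e (1.58), the histocompatibility gene H2-Ea (1.52), the splicing gene Cwc22 (1.51), Ibsp (1.45), the lubricin gene Prg4 (1.43), Rimbp2 (1.37) and Cyp2g1 (1.35) completed them. In 11 of the 20 genes the residuals fell into 2 groups of mice, 3.62 log2 apart for Defb3, 3.49 for S100a8, 3.46 for Cr2 and 2.84 for Cwc22. S100a8 followed the other stressed keratinocyte genes (r = 0.84 with the rest of its list). For Defb3 and S100a8 a single skewed group was not excluded. For genes such as Cr2 and Cwc22, transcript level was not separated from how well the probes hybridise to each parental allele.

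**Figure D5:**
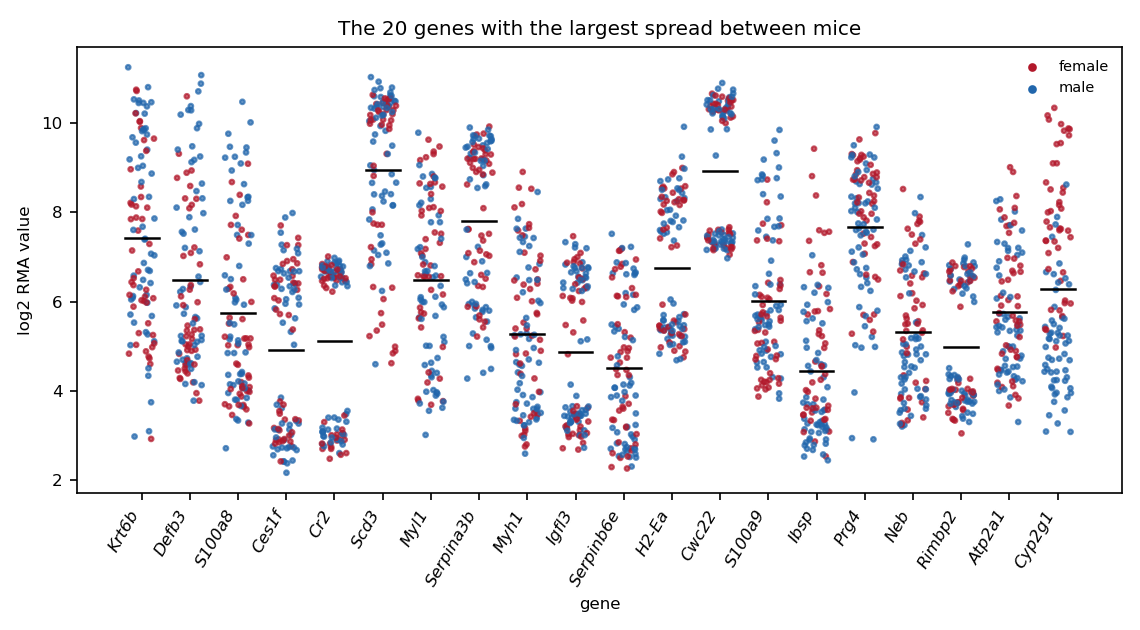
Log2 values of the 20 genes with the largest residual SD, 1 point per mouse (46 females red, 57 males blue), with a bar at each gene's mean. Krt6b spreads from 2.93 to 11.2, while values of Cr2, Igfl3, Cwc22 and Rimbp2 gather in 2 bands.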

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

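Only the settings that leave out the 2 arrays standing apart and that use only probe sets with 1 gene symbol were chosen after the result was seen. The number of probe sets that differed between the sexes, 666, was 975 with the marked arrays included, 633 without the plate term, 667 without the filter, 610 with the stricter filter, 660 after quantile normalisation, 687 with limma-trend, 903 without the arrays standing apart and 707 with 1-symbol probe sets. Of the original calls these kept 663, 612, 515, 522, 594, 659, 645 and 570. The stricter filter and the 1-symbol setting left out some probe sets before testing, so calls among those could not be kept. The count was 1016 with array weights, which kept 644, and the cause was not tested. With the first principal component as a covariate it was 1098, which kept 666. That component came from residuals after sex and plate, so it left each sex difference unchanged and altered only its error. Its count is therefore no independent check. Within plates it was 81, 43 and 6 for plates 1, 2 and 3, which hold fewer arrays, with 64, 40 and 5 of the original calls. Averaging the probe sets of a gene gave 697 genes, with p adjusted over genes alone, against 536 named genes in the analysis reported. The sex by plate interaction gave 1 probe set without the filter and 1 without the arrays standing apart; the cause was not tested. The plate test gave 4 or 5 probe sets in every setting run. Of 17 lists called between the sexes, 2 passed with an estimated correlation, which allows for the correlation within each list, 13 passed with fry, and between 16 and 18 in the other settings.

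On plate 3 alone, 11 of 58 named genes changed sign: Chad (-1.03), Hhip (-0.11), Car3 (-0.48), Tagln (-0.067), Tnmd (-0.031), Sprr2d (0.16), Krt14 (0.029), Tgm3 (0.017), Lss (0.049), Rras2 (0.091) and Nras (3.3e-05). Nras, at -0.001 in the analysis reported, was also 0.0015 with the marked arrays, 0.00054 without the plate term and 0.0013 after quantile normalisation. Without the filter camera's direction turned for antigen presentation (median difference 0.011) and macrophages (-0.0032), which passed in neither setting. For these reversals the cause was not tested. Of the 58 named genes, at least 55 kept direction and side of the threshold in each setting that used all plates and tested them all, and 46 of 47 with the stricter filter. On plates 1 and 2 alone 23 did, and 35 kept their direction without passing. Without the filter Gm11564, Car3 and Retn did not pass.

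Between 20 and 25 of 28 lists exceeded the random lists in their correlation in every setting. The mean correlation of heat shock genes changed sign with the marked arrays (-0.0032), after quantile normalisation (-0.0175), on plate 2 (-0.0155), on plate 3 (-0.0037) and in males (-0.0165). It also changed sign for tail scale keratins after quantile normalisation (-0.062), and on plate 3 for the interferon response (-0.074) and the Bmal1 arm (-0.013). Of 351 list pairs, 117 passed, against 60 on plate 1, 108 on plate 2, 1 on plate 3, 39 in females, 111 in males and 77 by Spearman's rho; the cause was not tested. With the first principal component removed 95 passed, 52 of them among the 117, and without the arrays standing apart 84 passed, 75 of them among the 117. The correlation of fibroblasts and matrix with smooth muscle was -0.0058 with the first principal component removed. That of Nras with ERK feedback, -0.06, was 0.22 on plate 2, 0.12 in females, 0.047 without the arrays standing apart and 0.071 by Spearman's rho; the cause was not tested. No paired analysis was possible because each mouse gave 1 array and the labels pair no mice. The 5 Ras relations with genes not analysed here were not run.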

Other observations

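The tests on list, interaction and plate counts under other splits, on both plate patterns (Y-linked signal in females and plates 1 and 2 included), on the composition of the samples and on cross-hybridisation were chosen only after the result was seen, and the test of weaker hybridisation was written after the signs of the nearest pairs were known.

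Residuals of 95 of 12197 autosomal genes placed along the chromosomes fell into 2 groups of mice. Over all genes in 2 groups there was a median of 45% of mice in the smaller group and a median distance of 0.99 log2. The groups of the antimicrobial gene Defb3 (3.62 log2 apart, 33.3% in the smaller group) and the calgranulin gene S100a8 (3.49, 32.2%) lay farthest apart on the log2 scale. The complement receptor gene Cr2 (3.46, 41.2%), Igfl3 (3.12, 48.8%), the histocompatibility gene H2-Ea (2.87, 49.5%), the splicing gene Cwc22 (2.84, 47.6%) and Rimbp2 (2.64, 41.7%) followed among others. Cr2, Igfl3, H2-Ea, Cwc22 and Rimbp2 varied with the nearest such gene on their chromosome, while Defb3, S100a8 and the collagenase gene Mmp13 did not. That gene lay next to Defb3 (0 measured genes between, r = -0.007), but 173 genes from S100a8 (r = -0.006) and 455 from Mmp13 (r = 0.10). Pairs with more than 200 genes between them had a median absolute correlation of only 0.25, so the case of Mmp13 says little. The BIC difference was 24.1 for Defb3, 17.8 for S100a8 and 11.3 for Mmp13, against 144 for Cr2. For those 3 genes a single skewed group was not excluded. In limma's test 0 of the genes in 2 groups were called between the sexes.

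The 2 arrays marked as outliers were set against the 57 other males in 27 lists. The lists farthest from the mean of those males are named first, and the like extremes of unmarked males were not computed. In male 40, melanocyte genes lay -5.33 SD from the mean of the other males, follicle stem cell genes -3.32, tail scale keratins -3.21 and fibroblast genes -2.70, while oxidative phosphorylation genes lay 3.61 SD above. In male 41, smooth muscle genes lay -2.61 SD, follicle stem cell genes -2.52, the Per and Dbp arm of the clock -2.18 and adipocyte genes -2.11 from it. Stressed keratinocyte genes lay above it in both arrays, by 2.29 SD in male 40 and 1.84 SD in male 41.

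Chance was excluded for the sex difference, where 1 of 100 splits, the real one, gave as many as 666 probe sets and the highest other gave 2. For lists, 1 of 100 splits, the real one, reached 17 and the highest other 12. The 17 include the X escape and Y-linked lists, which a split by sex is bound to call. The other 15 are still more than any other split called, but 96 of the 99 other splits called at least 1 list. A single camera call with the preset correlation is therefore weak evidence. For the interaction the count found was 0, which all 100 splits reach by construction, so the splits say nothing about it; the highest other gave 2. For plates 2 of 100 splits, the real one included, gave at least the 4 probe sets found, which excludes chance at 0.05, although the highest other split gave 14.

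Xist on plate 3 lay below, and Y-linked genes above, their values on the other plates. A shared fall in RNA quality or hybridisation is argued against, since Xist moved by -0.73 log2 and the 3 Y-linked genes moved the opposite way, and a difference in the mice themselves, since Eif2s3y was 0.68 ± 0.05 log2 (SE) higher on plate 3 in females, which carry no Y chromosome, Uty 0.68 ± 0.12 and Kdm5d 0.47 ± 0.11 (n = 6 against 40). A candidate explanation for plate 3 is that plate means were equalised without regard to sex before deposit, because plate 3 has 54.5% females against 44.7% and 42.2%: the slope of observed on predicted offsets was 1.01 (95% interval 0.85 to 1.18, too narrow because the 12 offsets are not independent), but it rests on plate 3. Plates 1 and 2 differed in the order opposite to the predicted one in all 4 genes, by 0.10 ± 0.06 for Xist (predicted -0.18), -0.02 ± 0.05 for Eif2s3y (0.14), -0.04 ± 0.05 for Uty (0.11) and -0.009 ± 0.05 for Kdm5d (0.088); the first 3 lie more than 2 SE from the prediction and Kdm5d does not, so the explanation stays open. Plates 1 and 3 held no marked arrays, yet their means were 6.522 and 6.359 for Xist and 5.715 and 5.837 for Eif2s3y. They were 5.07 and 5.223 for Uty and 5.085 and 5.109 for Kdm5d. These values argue against an exact equalisation for these 4 genes, while a less exact one stays open. The predicted offsets left out the marked males of plate 2. Against a wider trace of such an adjustment, 675 probe sets had an unadjusted plate p under 0.05, below the median of 1021 over 99 random assignments but within their range of 508 to 2714, so plates closer together than chance were not shown.

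Several lists of skin tissues were called between the sexes by camera with its preset correlation, although none of these calls held with an estimated correlation. One candidate explanation is that female samples held more muscle and deep tissue, another that they held more dermis. With the skeletal muscle list as a covariate 11 of 14 other called lists kept a difference above 2 SE, and with the fibroblast list 11 of 14, against 11 of 15 without a covariate. Differences of deeper tissues became smaller: tendon went from 0.47 to 0.32 with either covariate, smooth muscle from 0.21 to 0.14 and 0.15, mast cells from 0.19 to 0.15 and 0.12, and endothelium from 0.11 to 0.07 and 0.02. Neither list mean as a covariate therefore removed the whole pattern. The sex differences of the covariates themselves were within 2 SE, 0.44 ± 0.23 for skeletal muscle and 0.11 ± 0.07 for fibroblasts. Such list means measure the amount of deep tissue or dermis in a sample only roughly. The differences that remained can therefore exclude neither explanation, and both stay open. Hair cycle stage and a direct effect of sex stay open and were not tested.

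Many genes in 2 groups may reflect segregating parental alleles of the backcross: pairs with at most 50 measured genes between them had a median absolute correlation of 0.79, where the highest of 1000 shufflings gave 0.126 and pairs on different chromosomes 0.071. Cross-hybridisation of neighbouring gene copies is argued against as the whole cause, since pairs with 51 to 200 genes between them still had 0.63. Weaker hybridisation of one parental genome's sequence to the probes stays open, because 81.3% of these pairs had a positive correlation, as a loss of signal from one parent's alleles would give. Expression and hybridisation differences were not separated by these tests, and for Defb3, S100a8 and Mmp13, which did not vary with their nearest such neighbour, linkage gives no support to either.

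Around Hras, 0 of 100 genes fell in 2 groups, but a share of 0.474 of all windows had as few, and since so many windows hold 0 such genes the planned threshold of 0.05 was out of reach, so selection at Hras stays undecided.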
